A study of Arabidopsis thaliana with 20 samples.

How the data were processed

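The series holds 12 RNA-seq samples and 8 H3K27me3 ChIP-seq samples from the aerial parts of Arabidopsis thaliana seedlings of the Ws ecotype, aged 10 days at the start of treatment, after 0, 50 or 100 µM ABA for 5 h or 4 d. For the RNA-seq samples the authors deposited raw counts, reads per gene from HTSeq with no normalization. For the ChIP-seq samples the authors deposited peak lists with the caller's score per island from SICER 1.1, and this score is not comparable between lists. The labels name the TAIR10 build, FastQC and DESeq, and give no version for HTSeq, no aligner and no peak threshold. No raw reads were used. Samples were grouped by genotype, dose and time as the labels give them (for the 2 mock libraries at 5 h the source name alone gives the time, and the titles name none), which made 10 RNA-seq groups, of which WT and clf-50 swn-1 after 4 d of 100 µM ABA had 2 libraries each and the other 8 had 1.

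The count files list 33602 genes, and the libraries held 18911841 to 29887950 counts on genes. The 279 organelle genes were at 0 in every library and are outside all results. With edgeR 4.0.16 in R 4.3.3, genes with few counts were left out by filterByExpr over the groups (11684 genes, leaving 21918), libraries were scaled by TMM, and 1 quasi-likelihood model with 1 coefficient per group was fitted to all 12 libraries. It leaves 2 residual degrees of freedom, both from the replicates of 4 d of ABA, so the lone library of every other group is assumed to vary like these. The biological coefficient of variation was 0.295. The 6 contrasts were ABA against mock at 4 d in WT and in the double mutant, the double mutant against WT under ABA at 4 d, the interaction of genotype and ABA at 4 d, the double mutant against WT in mock averaged over 5 h and 4 d, and ABA against mock at 5 h averaged over both genotypes. P-values were two-sided and adjusted by the Benjamini-Hochberg method over the genes tested in each contrast, with a false discovery rate of 0.05 as the threshold. The standard error of a log2 fold change was its size divided by the square root of its F statistic. A gene with 0 counts in a group is given as at least a fold against a floor of 3 counts over that group, and with 1 to 3 counts as a ratio of scaled counts with its exact 95% interval for counting error.

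Comparisons of 1 library with 1 library carry no test. They use log2 ratios of scaled CPM with a prior count of 2 and count genes with a mean of at least 5 CPM that differ at least 2-fold. A list's median was set beside 10000 random lists of the same size and matched expression.

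The 18 gene lists, the genes to be named, the contrasts, the tests and the first set of other settings were fixed before the data were examined. The lists cover senescence-associated genes, chlorophyll breakdown, autophagy, ABA-responsive genes, ABA receptors, clade A PP2C phosphatases, ABA synthesis and breakdown, photosynthesis, embryo and seed maturation, floral homeotic and flowering genes, meristem and boundary genes, Polycomb and H3K27 demethylase genes, mitotic cell cycle, root markers, jasmonate response, salicylic acid and defence, anthocyanin synthesis, and reference genes. Of 253 entries, 4 did not match a name in the reference and were left out, and 238 were tested. Lists were tested with camera from limma 3.58.1 on log2 CPM with a preset correlation between genes of 0.01, adjusted over 108 pairs of list and contrast, and again with an estimated correlation. Members were also counted after adjustment over the list alone. The genes named are CLF and SWN, reference genes, up to 4 members per list with the smallest p and at least 1 CPM in a library, and the 5 largest rises and falls past the threshold with a mean of at least 5 CPM and no overlap between the compared libraries. In comparisons of single libraries they are the members with the largest ratios. Genes outside this rule are marked in the text as chosen after their values were seen.

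Peaks were compared with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9. The overlap of lists at 5 h was measured as the Jaccard index of covered bases. A peak was gained or lost when it shared no base with the other list, and a gene when at least 50% of its length was covered in 1 list and under 10% in the other. Marked genes were covered over at least 50% of their length in all 4 mock lists and unmarked genes had no covered base in any of them. Marked and unmarked genes were compared by a two-sided Fisher's exact test among genes tested for expression and by camera, and the genes induced at 5 h by permutation of the class over genes. The gene table names the TAIR10.1 assembly while the labels name TAIR10, so the positions were checked by shifting the peaks by up to 10000 bp in each of 20 chromosome segments. In 19 of 20 segments the expression of covered genes relative to uncovered ones was lowest within 500 bp of no shift, and in the other it was lowest at 1500 bp. The median difference was −4.02 on the log2 scale with no shift and −0.06 at far shifts.

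The pipeline was tested on simulated data with dispersions drawn around the fitted trend, 21918 genes and 200 changed genes per contrast. Genes were drawn independently, unchanged genes had the same mean in all groups, and changed genes had a mean of at least 5 CPM. The shares below need not hold in the real data, where genes are correlated, and do not test the list test for correlated genes. Of genes changed by 4 on the log2 scale 90% and 66% were recovered for ABA at 4 d in WT and in the double mutant, 94% for the double mutant against WT under ABA and 46% for the interaction. Of genes changed by 2 the shares were 20%, 14%, 58% and 0%, and of genes changed by 1 none was recovered in any contrast. False calls numbered 1 to 7 per contrast. A list of 25 genes shifted by 1 in the interaction gave a camera p of 5.92e-10, and 0.0204 with an estimated correlation. The estimate rests on the 2 residual degrees of freedom, so a call lost with it does not show that a list was unchanged. All 20 simulated peak overlaps gave the known answer.

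The alternatives tried were another normalization (RLE), no filter on low counts, DESeq2 1.42.0, limma voom, a 2-fold minimum, each replicate left out in turn, other mock libraries as control, a replicate block, a fit of 4 libraries, an additive model, other prior counts and CPM minimums, fry and an estimated correlation for lists, and other thresholds for peaks, overlap and marked genes. Alternatives added after the data were seen were the lists with replicates left out and with RLE, the marked genes with replicates left out, the mock list of the other dose, the 5000 peaks of highest score, and the counts without the genes around CLF.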

Results

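The series measured gene expression and H3K27 trimethylation in the aerial parts of 10-day-old Arabidopsis thaliana seedlings of the Ws ecotype after transfer to medium with abscisic acid (ABA), a stress hormone that promotes leaf senescence. H3K27me3, a histone mark of Polycomb-repressed genes, is written in seedlings by the methyltransferases CLF (AT2G23380) and SWN (AT4G02020), and the mutants were clf-50, swn-1 and the double mutant clf-50 swn-1. The 12 RNA-seq libraries fell into 10 groups. WT and the double mutant each had 1 mock library at 5 h, 1 library after 5 h of 100 µM ABA, 1 mock library at 4 d and 2 libraries after 4 d of 100 µM ABA, while clf-50 and swn-1 each had 1 mock library at 4 d. The titles of the 2 mock libraries at 5 h name no time, and 5 h was taken from their source names. The comparisons at 5 h and part of the mock comparison of the genotypes rest on it. The other 8 samples were H3K27me3 peak lists. There were 2 lists each for mock and 50 µM ABA at 5 h, and at 4 d 1 list each for 50 µM ABA, 100 µM ABA and the mock sample made for each dose. The labels give no genotype other than Ws for the peak lists and do not say whether replicates came from separate cultures. The p-values therefore measure only the spread between these samples, and intervals from counts cover counting error only. In the fit of the RNA-seq libraries that spread comes from the replicates of 4 d of ABA alone.

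The RNA-seq libraries held 18911841 to 29887950 reads on genes, and 21918 of 33602 genes were tested. Replicate 1 of the double mutant after 4 d of ABA stood apart from the other 11 libraries. Its share of reads on more than 1 gene was 3.48%, and on the first principal component, which held 43.0% of the variance, it lay at 183 against 107 for replicate 2. The replicates correlated across genes at r = 0.980 in WT and r = 0.960 in the double mutant, where genes are not independent replicates. Fold changes are given as log2 values from the edgeR fit with their standard errors.

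CLF had 0 counts in all 6 libraries that carry clf-50, against 19.7 to 35.6 CPM (read counts scaled by library size) in the other 6. SWN lay at 216 to 335 CPM in the 6 libraries that carry swn-1 and at 37.2 to 68.8 CPM in the others. Counts per gene do not show whether the swn-1 transcript is intact. Among the genes often used as references, UBC21 lay at 24.9 to 44.5 CPM, PP2AA3 at 57.0 to 76.8 CPM and ACT2 at 265 to 532 CPM in all 12 libraries. UBQ10, a polyubiquitin gene, reached 2620 and 1740 CPM in the double mutant after 4 d of ABA and lay at 943 to 1570 CPM elsewhere.

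CLF was not the sole gene near 0 in the libraries with clf-50. Of 17284 genes with at least 1 CPM in each of the 6 other libraries, 11 had a mean in the clf-50 libraries under 2% of that in the others. Of these 11, 10 lay within 1 stretch of 16 neighbouring genes: AT2G23300, ATRER1C1, WRKY15, DEAR3, PAB4, AT2G23360, AT2G23370, CLF, AT2G23390 and NAPRT2. Each of the 10 was at 0.344% or less of its mean elsewhere, while the pseudogene AT2G23330 in the same stretch was at 335%. These neighbours were chosen after their values were seen. They account for 10 of the 22 genes called lower in the double mutant without ABA and for 10 of the 692 called lower under ABA. The gene outside the stretch was AT3G16670.

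**Figure D1:**
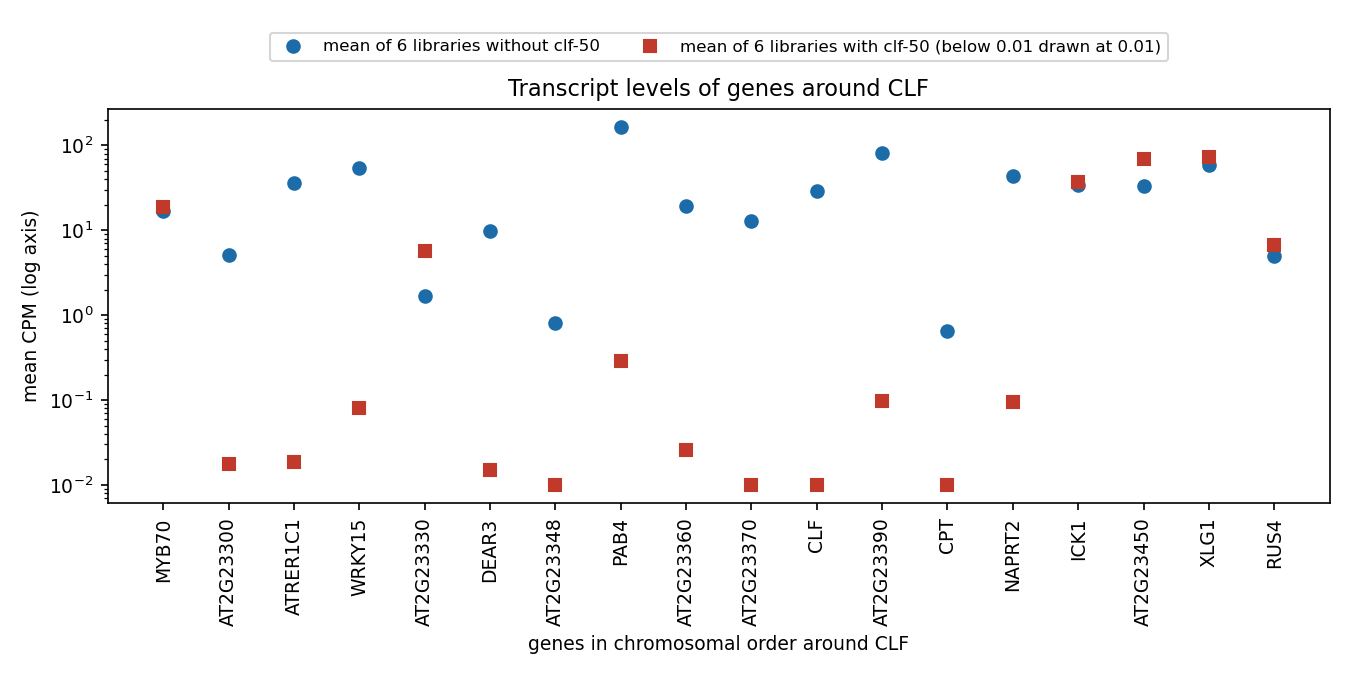
Mean CPM (log axis) of genes around CLF with at least 0.5 CPM without clf-50, in the 6 libraries without clf-50 and the 6 libraries with it, in chromosome order; values below 0.01 are drawn at 0.01. The 10 near-silent genes lie within 1 stretch of 16 genes.

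Without ABA, the question was which genes differ between clf-50 swn-1 and WT. Each side holds its mock libraries of 5 h and 4 d, which were averaged and are not replicates. The standard errors rest on the replicates of 4 d of ABA and do not measure the spread between these mock libraries. The floral list had the largest median of the 18 lists. The MADS-box floral organ identity genes AG, AP3 and PI rose by 7.77 ± 0.29, 7.27 ± 0.35 and 6.18 ± 0.30, and FLC, a repressor of flowering, rose by 4.11 ± 0.28 (n = 2 against 2). The floral list had a median of 4.5 and 17 of 18 members higher, of which 9 rose over all genes and 15 rose when adjusted over the list alone. SOC1 was lower in that second adjustment. Shoot meristem regulators moved the same way: the meristem and boundary list had a median of 1.93, and 9 of 11 members rose when adjusted over the list alone, against 0 over all genes, among them KNAT2 (2.01 ± 0.31), STM (2.32 ± 0.46) and KNAT1 (1.52 ± 0.31). VSP1 and VSP2, vegetative storage protein genes induced by jasmonate, rose by 5.25 ± 0.36 and 4.63 ± 0.31.

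Several other lists were shifted in that comparison. The camera test called the lists for floral genes (adjusted p = 3.14e-18), embryo and seed maturation (median 3.56, adjusted p = 1.23e-08), photosynthesis (median −0.73, adjusted p = 1.09e-07), meristem genes (adjusted p = 6.06e-06), ABA response (median 0.95, adjusted p = 0.000293), jasmonate response (median 0.80, adjusted p = 0.000453), anthocyanin synthesis (median 1.56, adjusted p = 0.000944) and ABA synthesis and breakdown (median 0.65, adjusted p = 0.0237). None of these calls held with an estimated correlation between genes (adjusted p = 0.757 to 0.807 with an estimated correlation). That estimate rests on 2 residual degrees of freedom, and a simulated list shifted by 1 reached a camera p of 0.0204 with it. Here and in the other comparisons, a call lost in this way does not show that a list was unchanged. All 27 photosynthesis genes were lower, with no member past either threshold. Adjusted over the list alone, 5 of 25 ABA-responsive genes rose against 0 over all genes, including the cold- and ABA-inducible gene KIN1 (2.41 ± 0.42) and the late embryogenesis gene LEA7 (3.60 ± 0.69). The same adjustment gave 4 of 11 jasmonate genes against 2 over all genes, 5 of 7 anthocyanin genes against 0, and BGLU18 alone among 13 ABA metabolism genes (2.60 ± 0.42) against 0. Of the 15 embryo genes tested, 1 rose in that adjustment, ABI5 (3.12 ± 0.44), against 0 over all genes, and the list median was 3.69 with genes of few counts at their bound. The embryo difference came from 5 h, where the median of the single libraries was 4.42, against 0.00 at 4 d. The seed storage gene CRU3 had 2365 counts in the double mutant, all in the library of 5 h, and 3 in WT, a ratio of 711 (95% interval 243 to 3450). Anthocyanin genes followed the same division, with a median of 3.19 at 5 h and 0.07 at 4 d, and jasmonate genes in part, with 1.68 and 0.35. Senescence-associated genes had a median of 0.13 (adjusted p = 0.804). GLN1;4, a cytosolic glutamine synthetase gene of nitrogen remobilisation, fell by 3.92 ± 0.34 over all genes, and adjusted over the list alone 1 member rose (XTH24, 1.96 ± 0.32) and 2 were lower (GLN1;4 and SEN1, −2.15 ± 0.39). The SEN1 difference came mainly from 5 h, with 26.6 CPM in the double mutant against 463 in WT, while at 4 d the values were 356 and 402 CPM. Root markers had a median of −2.21 (adjusted p = 0.0501), or −1.82 with genes of few counts at their bound, and the fall came from 4 d, where the single libraries gave −2.02 against 0.19 at 5 h.

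In all, 71 genes were higher and 22 lower in the double mutant without ABA at a false discovery rate under 0.05. All 93 showed no overlap between the 2 double mutant and the 2 WT libraries, as did 41.3% of all tested genes, where chance gives 33.3%. Besides the genes around CLF, the largest rises were at AT1G47980 (at least 428-fold), AT2G10975 (at least 234-fold) and AT1G20500 (at least 189-fold), which had 0 counts in WT, and at AT3G11165 (ratio 543, interval 97.1 to 21500) and AT4G08405 (ratio 873, interval 241 to 7220). The largest falls were at ATRER1C1 (at least 573-fold), CLF (at least 521-fold) and AT2G23370 (at least 205-fold), where such bounds set 0 counts over a group at a floor of 3 counts, and at AT3G16670 (−11.88 ± 0.50) and AT2G23390 (−10.16 ± 0.77). In the Polycomb list (median −0.01, adjusted p = 0.802), SWN (2.61 ± 0.26) rose over all genes, and EMF1 (1.64 ± 0.20) and MEA rose when adjusted over the list alone. MEA had 41 counts against 0, at least 12.3-fold. DESeq2 called 864 genes and limma voom 94. The count was 0 without either WT ABA replicate and 1001 or 826 without replicate 1 or 2 of the double mutant under ABA, libraries that enter this comparison through the estimate of spread alone.

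The single mutants were compared with WT in mock at 4 d as single libraries, with no test. In clf-50, 500 genes differed at least 2-fold, of which 301 were higher, against 164 and 40 in swn-1 and 1800 and 868 in the double mutant; the 2 WT replicates under ABA differed at 624 genes and the 2 double mutant replicates at 1617. The floral list median was 1.68 in clf-50, above all 10000 random lists of matched expression, −0.08 in swn-1 and 4.05 in the double mutant. AG was higher by 7.04 in clf-50 and lay at −0.66 in swn-1. AP3 stood at 4.09 and −0.22 and FLC at 3.32 and 1.43 in the same order. The root marker list median was −1.82 in clf-50, below all random lists. It rests mostly on few reads: in the WT library EXPA7, RHD6, COBL9, NRT2.1, EXP18 and WOX5 had 5 to 16 counts, or 0.186 to 0.596 CPM. CASP1 and BGLU23 had 67 and 8866 counts in WT and 14 and 3751 in clf-50. The same WT library enters the root marker median of the double mutant. The ABA-responsive list median was 0.83 in clf-50, above all random lists, and the senescence list median was 0.53. In the double mutant at 4 d the photosynthesis list lay at −0.93, the meristem list at 1.54 and the root markers at −2.02.

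**Figure D2:**
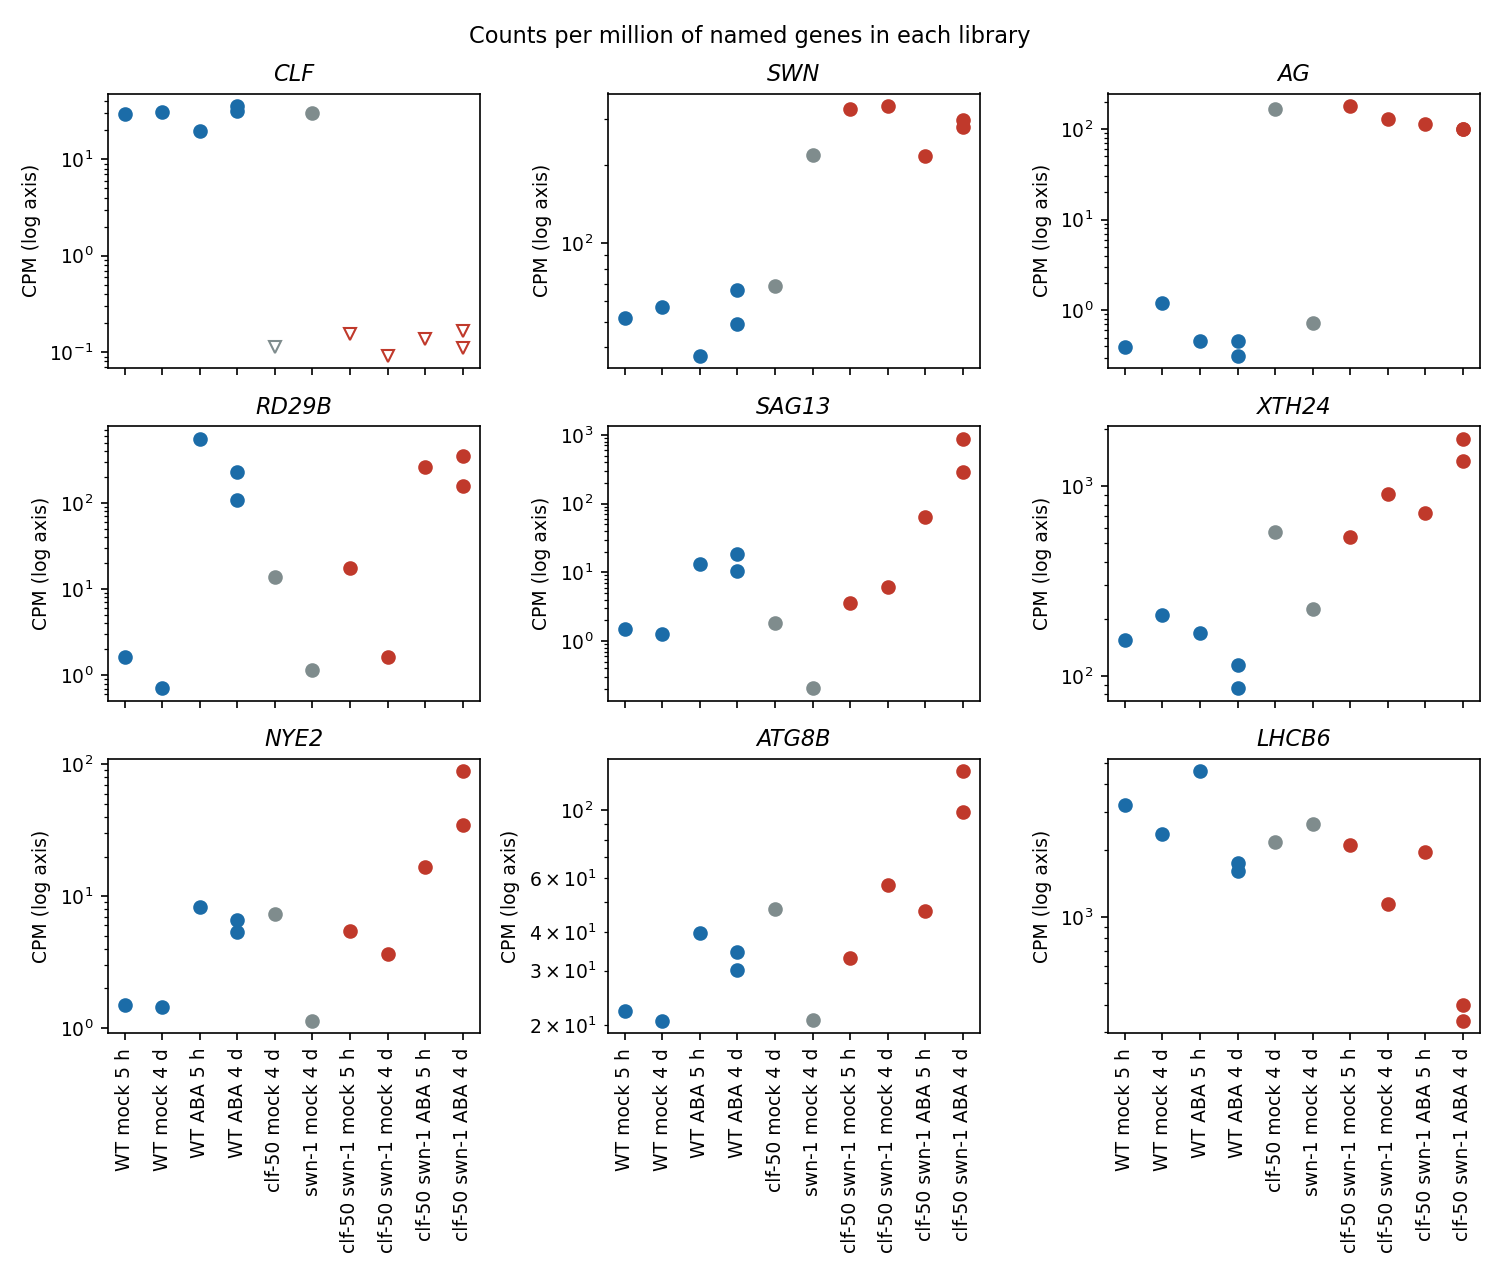
CPM (log axis) of 9 genes in each of the 12 libraries, with WT in blue, single mutants in grey and the double mutant in red; open triangles mark values below 3 counts, drawn at that floor. CLF has 0 counts in all 6 libraries with clf-50.

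After 5 h of ABA, compared with mock over both genotypes, canonical ABA-responsive genes were higher and ABA receptor genes lower. Each side holds a WT and a double mutant library, which were averaged and are not replicates. The standard errors again rest on the replicates of 4 d of ABA. Adjusted over the list alone, 21 of 25 ABA-responsive genes rose, against 0 over all genes, with KIN1 at 4.84 ± 0.37, LEA7 at 7.14 ± 0.65, RD29B at 6.15 ± 0.67 and XERO2 at 3.36 ± 0.41 (n = 2 against 2). Of the 9 clade A PP2C phosphatases, which restrain ABA signalling, 8 rose in that adjustment, against 0 over all genes, with HAI2 at 7.18 ± 1.14, HAI3 at 8.15 ± 1.37 and ABI2 at 3.08 ± 0.57. The ABA 8'-hydroxylase genes CYP707A1 (5.64 ± 0.50) and CYP707A2 (2.88 ± 0.29), which act in ABA breakdown, rose in the same way, against 0 over all genes. All 9 receptor genes were lower, with 0 past either threshold in edgeR and 5 at an unadjusted p under 0.05; PYL6 lay at −5.64 ± 1.23 and PYL2 at −1.88 ± 0.48.

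The camera test called 9 lists at 5 h. They were ABA response (median 3.03, adjusted p = 3.12e-15), PP2C phosphatases (median 3.08, or 2.95 with genes of few counts at their bound, adjusted p = 6.06e-06), jasmonate (median 0.88, adjusted p = 0.000143), anthocyanin (median 1.79, adjusted p = 0.000503), ABA synthesis and breakdown (median 1.67, adjusted p = 0.000504), senescence (median 0.91, adjusted p = 0.00201), ABA receptors (median −1.03, adjusted p = 0.00268), autophagy (median 0.48, adjusted p = 0.0032) and Polycomb (median −0.29, adjusted p = 0.00428). All 9 calls were lost with an estimated correlation (adjusted p = 0.757 to 0.807 with an estimated correlation). Adjusted over the list alone, 4 of 24 senescence genes rose against 0 over all genes: SWEET15 (6.77 ± 1.15), SAG13 (3.66 ± 0.69), WRKY45 (2.21 ± 0.43) and HAI1 (5.62 ± 1.09), a phosphatase that is also in the PP2C list. The same adjustment gave 3 of 11 jasmonate genes, led by VSP2 (3.48 ± 0.29), and 4 of 7 anthocyanin genes, each against 0 over all genes. EMF1 (−1.0 ± 0.20) and the H3K27 demethylase gene REF6 (−0.92 ± 0.19) were lower among 15 Polycomb and demethylase genes, again against 0 over all genes. The photosynthesis list had a median of 0.03 (adjusted p = 0.669). Of 15 embryo genes, EM6 rose in the list alone (7.97 ± 0.82), against 0 over all genes, while the list median was −0.34 (adjusted p = 0.102), or −0.58 with genes of few counts at their bound. CRA1 and CRU3 had 796 and 2366 counts in mock and 2 and 1 after ABA. In mock these came almost wholly from the 1 double mutant library, at 40.6 and 121 CPM, against 0.0496 CPM for each in WT.

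Over all genes, 2 rose at 5 h, ZW9 (6.04 ± 0.27) and PELPK1 (4.66 ± 0.22), both at an adjusted p of 0.0394 and higher in both ABA libraries. All pairs of ABA and mock libraries at 5 h were without overlap for 49.2% of tested genes, where chance gives 33.3%. At an unadjusted p under 0.05, 3847 genes differed; DESeq2 called 1020 and limma voom 0. Without WT ABA replicate 1 or 2 of 4 d, which set the spread, the count was 0, and without double mutant replicate 1 or 2 it was 1059 or 770. As single libraries, 1183 genes were at least 2-fold higher and 824 lower in WT, against 962 and 453 in the double mutant. The ABA-responsive list median was 3.46 in WT and 2.21 in the double mutant, that of the PP2C phosphatases 3.40 and 2.21, and that of the receptors −1.20 and −0.85. The difference between the genotypes at 5 h was not tested, since each side is 1 library.

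After 4 d of ABA in WT, ABA-responsive genes stood far above mock, while photosynthesis genes were slightly lower and senescence genes went both ways. Adjusted over the list alone, 15 of 25 ABA-responsive genes rose, with KIN1 at 8.29 ± 0.67, LEA7 at 9.63 ± 1.04, RD29B at 7.90 ± 1.03 and COR15A at 4.64 ± 0.59 (n = 2 against 1). In the same adjustment 5 of 9 PP2C genes rose, among them HAI2 (7.71 ± 1.62), PP2CA (2.99 ± 0.74) and ABI2 (2.64 ± 0.75), and 4 of 9 receptors were lower: PYL8 (−1.48 ± 0.22), PYL5 (−4.68 ± 0.81), PYL6 (−6.05 ± 1.26) and PYL2 (−2.15 ± 0.47). HAI3 had 474 counts against 1, a ratio of 211 (interval 37.8 to 8370). Among senescence genes SWEET15, a sugar transporter gene, rose (8.62 ± 1.74), while GLN1;4 (−3.75 ± 0.36), the dark-inducible gene SEN1 (−3.36 ± 0.44) and the asparagine synthetase gene ASN1 (−1.77 ± 0.29) were lower. CYP707A1 (4.60 ± 0.65) and CYP707A2 (2.71 ± 0.37) rose among 13 ABA metabolism genes. Over all genes 0 members of any of these lists passed in edgeR.

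The camera test called the lists for ABA response (median 3.08, adjusted p = 3.12e-15), photosynthesis (median −0.58, 27 of 27 lower, adjusted p = 6.39e-07), receptors (median −1.58, adjusted p = 8.91e-07), PP2C (median 2.64, adjusted p = 9.26e-06), root markers (median 2.58, adjusted p = 0.000453), anthocyanin (median 1.41, adjusted p = 0.00148), embryo (median 2.55, adjusted p = 0.0176), ABA metabolism (median 1.39, adjusted p = 0.0206) and floral genes (median −0.48, adjusted p = 0.0332). Each was lost with an estimated correlation (adjusted p = 0.757 to 0.807 with an estimated correlation). With genes of few counts at their bound the medians were 0.42 for embryo, 1.16 for ABA metabolism and −0.57 for floral genes. Without WT replicate 2 the ABA metabolism list lay at 0.44 (adjusted p = 0.174), and without WT replicate 1 the embryo list lay at 0.86. The floral call ended without WT replicate 1 (adjusted p = 0.204) and without replicate 1 or 2 of the double mutant (adjusted p = 0.0751 or 0.0845). All 8 root markers were higher although aerial parts were harvested, with COBL9 at 3.43 ± 0.86. No root, anthocyanin, photosynthesis or floral gene passed even when adjusted over the list alone, and among embryo genes EM6 did, with 206 counts against 1 (ratio 91.9, interval 16.3 to 3650). The senescence list had a median of 0.35, or 0.50 with genes of few counts at their bound, a positive mean of 0.62 and a negative camera direction (adjusted p = 0.804). Among jasmonate genes (median 0.47, adjusted p = 0.152) VSP2 rose by 2.60 ± 0.37 and the defensin gene PDF1.2 was lower (−3.79 ± 0.83) when adjusted over the list alone, against 0 over all genes.

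Over all genes edgeR called 0 genes after 4 d of ABA in WT, with a smallest adjusted p of 0.062. At an unadjusted p under 0.05, 1057 genes were higher and 814 lower; DESeq2 called 487 genes and limma voom 0. The count was 0 without WT replicate 1 or 2, and 326 and 215 without replicate 1 and 2 of the double mutant, libraries that enter through the spread alone.

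After 4 d of ABA in the double mutant, ABA-responsive, anthocyanin, senescence and chlorophyll breakdown genes were higher than in mock. SAG13, a senescence-associated dehydrogenase gene, rose by 6.56 ± 1.03 and SWEET15 by 8.80 ± 1.70, while SAG12, a cysteine protease gene of late senescence, had 125 counts against 1 in mock (ratio 89.5, interval 15.8 to 3560). Adjusted over the list alone, 9 of 24 senescence genes rose and 2, ASN1 (−1.84 ± 0.29) and SEN1 (−2.37 ± 0.44), were lower. Of 8 chlorophyll breakdown genes 5 rose, among them NYE2 (4.09 ± 0.74), NYE1 (3.34 ± 0.77), PPH (2.47 ± 0.50) and PAO (2.78 ± 0.65), which act in chlorophyll degradation. All 7 anthocyanin genes rose, with LDOX at 4.41 ± 0.78 and CHS at 3.10 ± 0.60. So did 17 of 25 ABA-responsive genes, with KIN1 at 4.97 ± 0.52, LEA7 at 7.86 ± 0.90, RAB18 at 6.31 ± 0.75 and RD29B at 7.27 ± 0.98. The same adjustment gave 6 of 9 PP2C genes higher, 6 of 9 receptors lower (PYL5 −2.28 ± 0.75, PYL6 −3.09 ± 1.06, PYL8 −0.75 ± 0.22), 4 of 13 ABA metabolism genes higher and 3 of 15 embryo genes higher. In edgeR 0 members of these lists passed over all genes. Between the 2 double mutant replicates the senescence list median differed by 0.98, the chlorophyll list by 1.12 and the PP2C list by 1.56.

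Camera called the lists for photosynthesis (median −1.54, 27 of 27 lower, adjusted p = 5.73e-11), ABA response (median 2.73, adjusted p = 2.52e-10), anthocyanin (median 3.85, adjusted p = 2.37e-05), PP2C (median 2.59, adjusted p = 0.000109), senescence (median 1.84, adjusted p = 0.000819), chlorophyll breakdown (median 2.47, adjusted p = 0.000841), autophagy (median 0.98, adjusted p = 0.000841), mitotic cell cycle (median −1.96, adjusted p = 0.000875), receptors (median −1.42, adjusted p = 0.00169), meristem (median −0.89, adjusted p = 0.0108), embryo (median 2.41, or 2.69 with genes of few counts at their bound, adjusted p = 0.0213) and floral genes (median −0.58, adjusted p = 0.0272). No call held with an estimated correlation (adjusted p = 0.757 to 0.807 with an estimated correlation). The meristem list had a mean of 0.07, opposite in sign to its median and test. Without replicate 1 of the double mutant the medians were 1.73 for ABA response, 1.44 for PP2C, 1.03 for senescence, 1.63 for chlorophyll breakdown and 0.22 for embryo genes, and the meristem call ended (adjusted p = 0.117). Without replicate 2 they were −3.29 for mitotic and 0.98 for embryo genes, and the floral call ended (adjusted p = 0.0852). The replicates differed by −2.10 in the mitotic list, −1.90 in the root list and −0.62 in the photosynthesis list. No photosynthesis, autophagy or mitotic gene passed when adjusted over the list alone, where 21, 7 and 5 members had an unadjusted p under 0.05 in edgeR; RBCS1B lay at −1.90 ± 0.43 and LHCB4.2 at −2.04 ± 0.49. Root markers had a median of 2.56, or 1.38 with genes of few counts at their bound (adjusted p = 0.227). Among 10 salicylic acid and defence genes (median 0.51, adjusted p = 0.849), SARD1 was higher (1.88 ± 0.49) and PR5 (−2.48 ± 0.45) and ICS1 (−0.99 ± 0.25) lower when adjusted over the list alone, against 0 over all genes.

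Over all genes edgeR called 0 genes in the double mutant as well, with a smallest adjusted p of 0.0655; 2312 genes were higher and 2462 lower at an unadjusted p under 0.05. DESeq2 called 1919 and limma voom 0, and the count was 322 without double mutant replicate 1 and 4357 without replicate 2. Against the mock library of 5 h, ASN1 lay at 2.1, SEN1 at 1.37 and PYL5 at 0.37, opposite in direction. Across 15759 genes the responses of WT and the double mutant, which share no library, correlated with r = 0.623 and rho = 0.548.

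The comparison with replicates on both sides set the double mutant against WT after 4 d of ABA and addressed how far senescence differs between them. Senescence, chlorophyll breakdown, autophagy and floral genes were higher in the double mutant, and photosynthesis and cell cycle genes lower. SAG13 rose by 5.36 ± 0.71, from 10.3 and 18.4 CPM in the WT libraries to 883 and 290 CPM, and XTH24, a cell wall enzyme gene, by 3.97 ± 0.35 (n = 2 against 2). SAG12 had 125 counts against 0, at least 55.2-fold. SAG20 rose by 1.74 ± 0.27. Of the 24 senescence genes 6 rose over all genes and 12 when adjusted over the list alone, with 0 lower. Of the 8 chlorophyll breakdown genes 3 and 5 rose in the same order, including NYE2 (3.37 ± 0.52), NYC1 (3.90 ± 0.66), NYE1 (3.07 ± 0.57) and PAO (2.3 ± 0.48). All 13 autophagy genes rose when adjusted over the list alone and 2 over all genes, ATG8B (1.84 ± 0.24) and ATG8I (1.36 ± 0.25).

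Light-harvesting genes fell: of 27 photosynthesis genes 24 were lower when adjusted over the list alone and 2 over all genes, LHCB6 (−2.19 ± 0.39) and LHCB4.2 (−2.42 ± 0.44). Of 11 mitotic genes 10 were lower in the list alone and 0 over all genes, with CDKB1;1 at −2.64 ± 0.60 and PCNA1 at −2.27 ± 0.65. Of 8 root markers 7 were lower in the list alone and 0 over all genes, with COBL9 at −2.96 ± 0.63 and CASP1 at −3.98 ± 0.97. In the floral list AG (8.0 ± 0.30), AP3 (7.10 ± 0.34), PI (5.77 ± 0.30) and FLC (4.89 ± 0.29) rose, as did 12 of 18 members over all genes and 14 adjusted over the list alone, where SOC1 was lower (−1.18 ± 0.30). Of 7 anthocyanin genes 1 rose over all genes and 6 adjusted over the list alone, with LDOX at 2.87 ± 0.53 and CHS at 2.05 ± 0.43. ABA-responsive genes went both ways: over all genes RD20 rose (3.32 ± 0.61) and GolS2 (−3.92 ± 0.71) and COR15A (−2.04 ± 0.39) fell, and adjusted over the list alone 2 rose and 3 were lower, among them COR15B (−3.29 ± 0.70). Among receptors PYL8 rose over all genes (1.41 ± 0.19), and adjusted over the list alone PYL8, PYL5 (3.29 ± 0.72) and PYL6 (4.58 ± 1.16) rose and PYL2 (−1.55 ± 0.46) was lower. ICS1, which makes salicylic acid precursor, fell by 1.31 ± 0.22, the 1 defence gene past either threshold, and VSP1 rose by 1.70 ± 0.31, the 1 jasmonate gene past either threshold.

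Camera called the lists for floral genes (median 4.01, adjusted p = 2.52e-10), photosynthesis (median −1.74, adjusted p = 2.52e-10), autophagy (median 1.15, adjusted p = 8.6e-06), senescence (median 1.80, adjusted p = 1.16e-05), root markers (median −3.05, adjusted p = 0.00131), mitotic cell cycle (median −2.27, adjusted p = 0.00144), anthocyanin (median 2.80, adjusted p = 0.00288) and chlorophyll breakdown (median 1.96, adjusted p = 0.00589). With an estimated correlation no call remained (adjusted p = 0.757 to 0.807 with an estimated correlation). Without replicate 1 of the double mutant the medians were 0.83 for senescence, 1.29 for chlorophyll breakdown and −1.48 for mitotic genes, and without replicate 2 the mitotic median was −3.62. The lists for ABA response (median 0.57, adjusted p = 0.22), receptors (1.11, adjusted p = 0.145), PP2C (0.69, adjusted p = 0.348), ABA metabolism (0.36, adjusted p = 0.443), jasmonate (0.49, adjusted p = 0.186), meristem (0.56, adjusted p = 0.172) and reference genes (0.20, adjusted p = 0.669) were not called. Neither were salicylic acid and defence genes (0.06, adjusted p = 0.899), Polycomb genes (0.05, adjusted p = 0.606) and embryo genes (0.00, or −0.11 with genes of few counts at their bound, adjusted p = 0.726), where the median, mean and test direction differed in sign. In the Polycomb list SWN (2.32 ± 0.25) and EMF1 (1.74 ± 0.20) rose and CLF fell, over all genes and over the list alone.

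**Figure D3:**
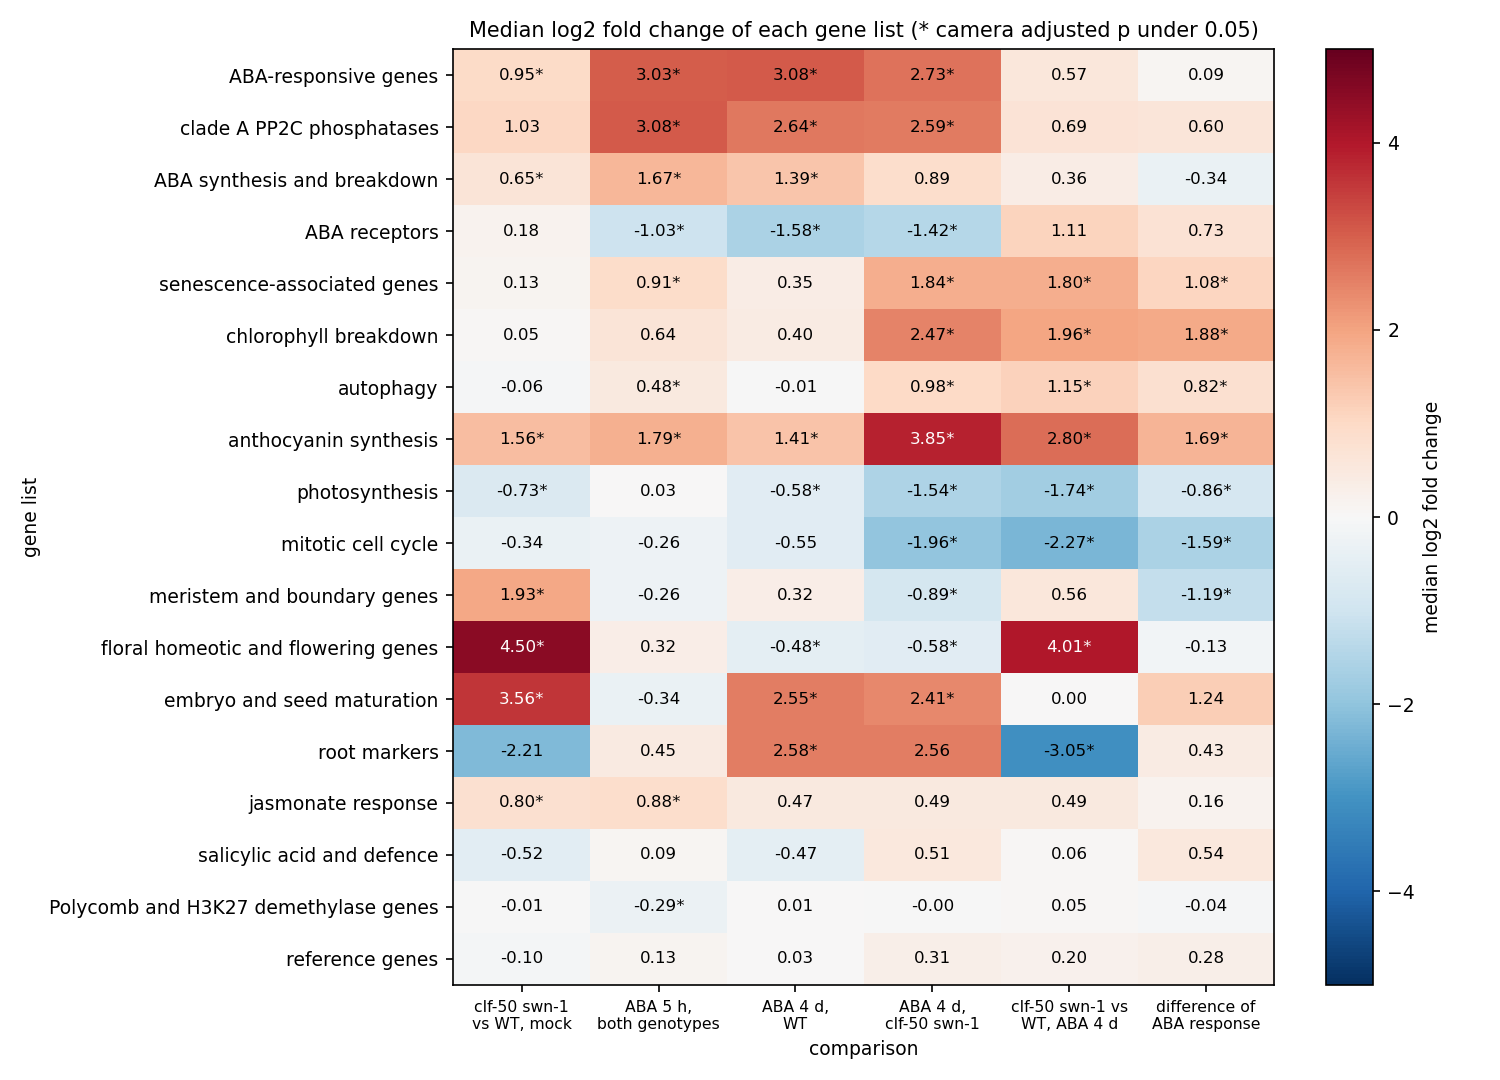
Median log2 fold change of the 18 gene lists in the 6 tested comparisons; colour and printed value give the median, and * marks an adjusted camera p under 0.05 with a preset correlation of 0.01. No marked cell kept its call with an estimated correlation.

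In all, 785 genes were higher and 692 lower in the double mutant under ABA. All 1477 lacked overlap between the compared libraries, as did 68.6% of all tested genes, where chance gives 33.3%. The largest rises were at AT4G00160 (at least 225-fold), AT3G11165 (810 counts against 2, ratio 536, interval 148 to 4440), AT5G28888 (ratio 539, interval 184 to 2620, where the double mutant libraries differed, 23.1 ± 26.5 CPM, mean and SD), AT2G10980 (ratio 290, interval 98.7 to 1410) and AT4G08405 (8.11 ± 0.78). The largest falls were at CLF (at least 510-fold), AT2G23370 (at least 214-fold), DEAR3 (at least 154-fold) and ATRER1C1 (1 count against 2199, ratio 0.000602, interval 1.52e-05 to 0.00336), which all lie in the stretch around CLF, and at BHLH100 (−10.31 ± 0.40), a regulator of the iron deficiency response. The difference under ABA correlated across 15759 genes with that in mock, which shares no library with it (r = 0.637, rho = 0.557). In both comparisons 62 genes were higher (2.54 expected by chance), 20 were lower (0.695 expected) and 0 went opposite ways. Of the 20 lower genes, 10 were those of the stretch around CLF. DESeq2 called 4355 genes and limma voom 2856. Without WT replicate 1 or 2 the count was 0, without double mutant replicate 1 it was 2069 and without replicate 2 it was 6663.

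The interaction asked whether the response to 4 d of ABA itself differs between the genotypes, the question in the series title. GLN1;4 was the 1 senescence gene past the test adjusted over the list alone (4.78 ± 0.56, adjusted p = 0.00824, 2 ABA libraries and 1 mock library per genotype): it fell in WT and had few reads in every double mutant library, 0.983 to 2.16 CPM. Across the senescence list the difference was mostly positive, with 21 of 24 members above 0, GLN1;4 included, XTH24 at 1.84 ± 0.55 and SAG13 at 3.07 ± 1.13. All 13 autophagy genes and 7 of 8 chlorophyll breakdown genes were above 0 and all 27 photosynthesis and 11 mitotic genes below, with no member past either threshold. VSP1 (−2.51 ± 0.54) and VSP2 (−2.11 ± 0.46) passed when adjusted over the list alone (adjusted p = 0.032 for both). Their fitted responses were 1.43 ± 0.40 and 2.60 ± 0.37 in WT and −1.08 ± 0.36 and 0.48 ± 0.33 in the double mutant, where neither passed.

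Camera called the differences for photosynthesis (median −0.86, adjusted p = 1.01e-05), senescence (median 1.08, adjusted p = 1.24e-05), autophagy (median 0.82, adjusted p = 4.73e-05), meristem (median −1.19, adjusted p = 0.000504), chlorophyll breakdown (median 1.88, adjusted p = 0.000586), anthocyanin (median 1.69, adjusted p = 0.00205) and mitotic genes (median −1.59, adjusted p = 0.00454). Each was lost with an estimated correlation (adjusted p = 0.757 to 0.807 with an estimated correlation). The anthocyanin difference rested on the mock pair of 4 d, whose median was 0.07: that of the 5 h mock pair, 3.19, lay within the range of the pairs under ABA, 1.67 to 3.81, and against the 5 h mock LDOX lay at −0.31. The senescence median was 0.91 with genes of few counts at their bound, 0.48 without double mutant replicate 1 and 0.58 without WT replicate 1. Without double mutant replicate 1 the medians were 0.53 for autophagy, 1.2 for chlorophyll breakdown and −0.89 for mitotic genes, and without replicate 2 they were −3.13 for mitotic and −2.28 for meristem genes. The ABA-responsive list was not called (median 0.09, or −0.09 with genes of few counts at their bound, with a negative mean and test direction, adjusted p = 0.804), nor were the receptors (median 0.73, adjusted p = 0.196). Root markers had a median of 0.43, or −1.45 with genes of few counts at their bound, and a negative test direction (adjusted p = 0.0829). Over all genes edgeR called 0 genes, with 1111 at an unadjusted p under 0.05, DESeq2 88 and limma voom 0. The count was 6 without double mutant replicate 1 and 24 without replicate 2.

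The H3K27me3 peak lists covered 20.7 to 23.7 Mb with 5647 to 7684 peaks. Mock at 5 h had 5647 and 6200 peaks and 50 µM ABA had 6013 and 6538. At 4 d, 50 µM ABA had 6031 peaks against 5889 in its mock list, and 100 µM ABA had 7684 against 7295. The lists hold no reads, so their depth is unknown. At 5 h the covered bases of 2 lists of the same treatment overlapped with a mean Jaccard index of 0.855 and lists of different treatments with 0.860. The difference of 0.0054 was smaller than the SD of 0.0094 between the within-treatment pairs, and 2 lists against 2 cannot reach a p below 0.333 in an exact permutation test. Lists of the same treatment always differed in replicate number. Lists of different treatments overlapped with 0.875 when they shared the number and with 0.845 when they did not. The sign of the difference thus depends on the replicate number, and these lists leave it undecided. Between same-numbered lists 347 and 283 peaks were in ABA alone and 187 and 198 in mock alone, while ABA covered 0.9645 and 0.9628 times the bases of mock.

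At 4 d more peaks were gained than lost against the mock list of the same dose, and receptor genes were among the genes that gained the mark. With 50 µM ABA, 467 peaks were gained and 162 lost, and with 100 µM ABA, 815 and 155. Genes covered over at least 50% of their length in 1 list and under 10% in the other numbered 283 gained and 121 lost with 50 µM, and 338 and 56 with 100 µM. The same 39 genes were gained with both doses (2.91 expected) and the same 11 were lost (0.206 expected). Genes chosen here after their values were seen include the receptor genes PYL5 (0 to 64.9% covered with 100 µM) and PYL6 (0 to 100%), gained with both doses, and PYL4 (0 to 55.6% with 100 µM). HAI1 went from 100% to 0 with 100 µM. ORE1 went from 39.6% to 0 with 100 µM, but it was covered under 50% in mock and does not count as lost. Among the genes lost with both doses was COR413IM1, which encodes a cold-regulated membrane protein.

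The same lists showed how far such changes arise without treatment. Between replicates at 5 h, 10 and 54 peaks were in replicate 1 alone and 827 and 853 in replicate 2 alone, for mock and ABA. The mock list made for 100 µM had 1025 peaks that the mock list for 50 µM lacked, and 107 were missing from it. Of the 39 genes gained with both doses 20 also separated replicates at 5 h, as did 5 of the 11 lost ones, against 2.03% of all genes. PYL5 and PYL6 are among genes that replicate 2 lists at 5 h covered in part: PYL6 was covered over 62.2% and 37.3% of its length there.

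**Figure D4:**
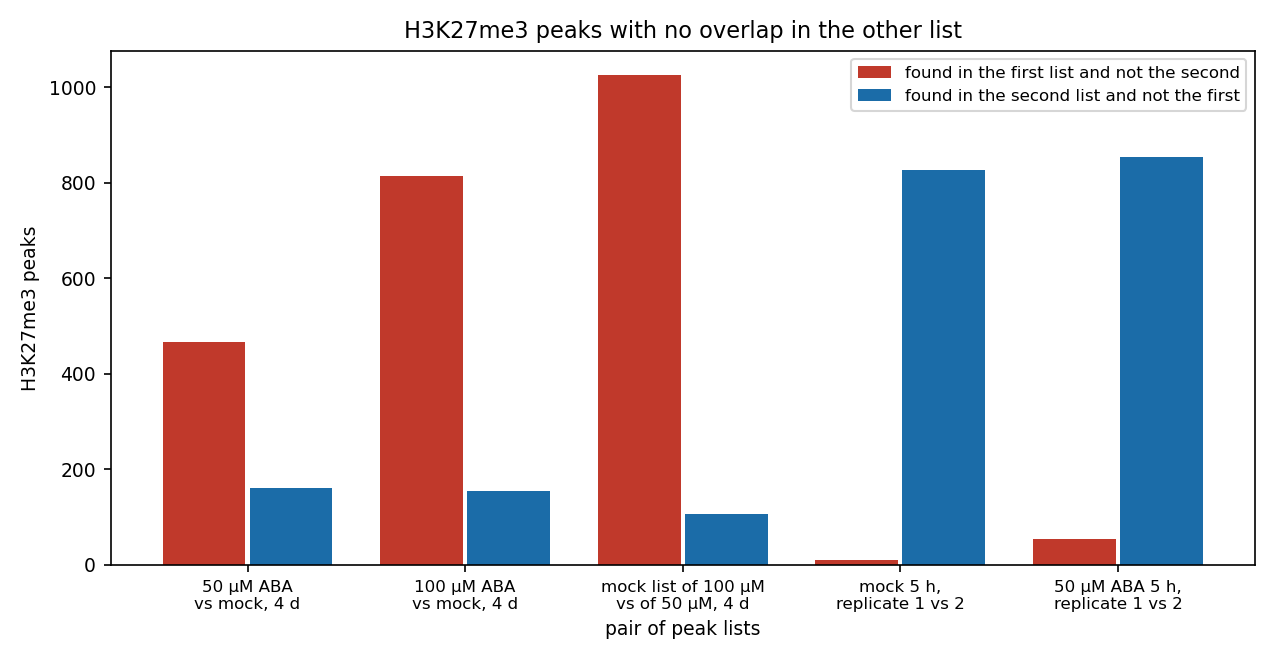
Number of H3K27me3 peaks gained and lost, as bars, for 50 µM and 100 µM ABA against mock at 4 d, for the mock lists of 4 d against each other and for the replicates at 5 h. The replicates at 5 h differ by up to 853 peaks in 1 direction.

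Genes that carried the mark in mock were called more often in the double mutant. Marked genes, covered over at least 50% of their length in all 4 mock lists, numbered 6175, or 18.8% of genes, and included all 18 floral genes, all 8 root markers, 20 of 23 embryo genes and 10 of 11 meristem genes. None of the 13 autophagy and 11 mitotic genes and 1 of 27 photosynthesis genes was marked, against 9 of 24 senescence and 11 of 25 ABA-responsive genes. Without ABA 1.36% of marked genes were higher in the double mutant against 0.128% of unmarked genes, an odds ratio of 10.7 (95% interval 6.24 to 18.9, two-sided Fisher's exact test with genes as units, p = 2.59e-20). Under ABA the shares were 7.47% and 2.60% for higher genes (odds ratio 3.02, interval 2.56 to 3.56, exact p = 7.8e-37) and 4.70% and 2.84% for lower genes (odds ratio 1.69, interval 1.39 to 2.04, exact p = 1.07e-07). Lower genes without ABA gave an odds ratio of 1.41 (exact p = 0.528). Changes of at least 2-fold were also more frequent among marked genes after 4 d of ABA in WT, where 31.8% were higher and 16.2% lower against 5.67% and 4.63% of unmarked genes. The shares in the double mutant against WT without ABA were 30.3% and 20.8% against 4.52% and 5.21%, so an excess of marked genes was not particular to the double mutant. Covered genes were also lower in expression than uncovered ones, with a median difference of −4.02 on the log2 scale. These shares and odds ratios were not matched for expression, so the mark cannot be told apart from low expression here. Without double mutant replicate 2 the ratio for higher genes under ABA was 1.71. Genes are not independent replicates, and as a set the marked genes were called by camera without ABA (adjusted p = 0.026) and after 5 h of ABA (adjusted p = 0.0015). Both set calls were lost with an estimated correlation (adjusted p = 0.918 with an estimated correlation). Between the genotypes under ABA camera gave no shift of the set (adjusted p = 0.998), with medians of −0.11 for marked and −0.03 for unmarked genes.

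Of the 1183 genes at least 2-fold higher after 5 h of ABA in WT, 321 were marked and 707 unmarked. After 4 d of ABA the marked ones stood higher against mock than the unmarked ones, in WT (medians 1.40 and 0.70) and in the double mutant (1.66 and 1.15). Both differences had a permutation p of 1e-05, the smallest that these permutations over genes can give. The permutations treat genes as independent and do not measure the spread of the 1 mock library per genotype. The classes were not matched for the rise at 5 h, where 156 of the 321 marked and 148 of the 707 unmarked genes had a log2 ratio of at least 2. Among these stronger genes the differences were 0.64 in WT and 0.73 in the double mutant. Between the genotypes under ABA the medians were 0.52 for marked and 0.71 for unmarked genes (permutation p = 0.067). For the interaction they were 0.17 and 0.36 (permutation p = 0.032), a difference of −0.19 that became 0.16 (permutation p = 0.61) for genes at a log2 ratio of at least 2. Genes that lost the mark with 100 µM ABA had a median of 0.91 after 4 d of ABA in WT, above all random lists (camera p = 0.000145; p = 0.305 with an estimated correlation), and those that gained it had −0.10 (camera p = 0.0486; p = 0.563 with an estimated correlation). No RNA-seq library had 50 µM ABA, so genes whose mark changed with 50 µM were read in the same expression data of 100 µM. There the medians were 0.41 for genes that lost the mark (camera p = 0.00252, and 0.251 with an estimated correlation) and 0.02 for those that gained it (camera p = 0.852). Expression was tested for 65 of 121 lost and 130 of 283 gained genes with 50 µM, and for 33 of 56 and 157 of 338 with 100 µM.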

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

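All tests of explanations in this part were chosen after the results were seen. The response to 4 d of ABA differed between the double mutant and WT in 7 gene lists by the camera test with a preset correlation, with median log2 differences of 1.69 for anthocyanin synthesis, 0.82 for autophagy, 1.88 for chlorophyll breakdown, −1.19 for meristem and boundary genes, −1.59 for mitotic cell cycle, −0.86 for photosynthesis and 1.08 for senescence-associated genes. None of the 7 held with an estimated correlation. Among single genes the difference passed, adjusted over the list alone, for GLN1;4 (4.78 ± 0.56), VSP1 (−2.51 ± 0.54) and VSP2 (−2.11 ± 0.46). Marked ABA-induced genes had a difference 0.19 lower than unmarked ones, that is −0.19, by permutation. Replicate 1 of the double mutant after 4 d of ABA had 3.48% of reads on more than 1 gene, against 2.4% to 2.7% in the other 11 libraries.

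The first pattern is the difference in the senescence, chlorophyll breakdown and photosynthesis lists between the double mutant and WT under ABA. A scaling error between libraries is argued against, since the senescence and photosynthesis medians lay 3.55 apart, and so is replicate 1 of the double mutant as the sole source for 2 lists: without it the pair nearest to 0 still gave 1.14 for chlorophyll breakdown and −1.32 for photosynthesis, where mock pairs gave 0.04 to 0.16 and −0.93 to −0.56. A genotype difference already there without ABA, as the sole source, is argued against for chlorophyll breakdown, where the ABA pairs exceeded the mock pairs by 1.76. It is not excluded for photosynthesis. There the excess was −1.02, but the mock pairs reached −0.93 against −1.32 for the nearest ABA pair. For both lists each mock pair is 1 library per genotype. For the senescence list both explanations stay open and cannot be told apart from an ABA effect, because the pairs under ABA ranged from 0.52 to 2.65 and their excess over mock, 1.46, is smaller than that range. A stronger senescence response in the double mutant, which the series title names, is a hypothesis that may hold but was found in the same libraries.

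The second pattern is the excess of gained over lost H3K27me3 peaks at 4 d, 2.88 to 1 with 50 µM and 5.26 to 1 with 100 µM. Depth or the calling threshold of the lists may account for it: replicates at 5 h, with no difference in treatment, differed by at least 15.8 to 1. The mock list used could account for the 50 µM result, since 139 peaks were gained and 724 lost against the other mock list. For the 100 µM result the other mock list gave 1613 gained and 107 lost. That list was the smaller one, with 5889 peaks against 7295, which by itself raises gains and lowers losses. This exchange therefore cannot decide whether the mock list used accounts for the 100 µM result. No biological explanation was tested, as 1 list per dose was made.

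The third pattern is the run of 10 near-silent genes around CLF in all 6 clf-50 libraries. Ws sequence variants against the reference would also affect the WT and swn-1 libraries, since all seedlings were of the Ws ecotype. In those libraries the lowest level of a run member was 2.77 CPM, and for all 10 genes every clf-50 library lay below every other library. The 10 members were chosen as expressed in the WT and swn-1 libraries and near-silent with clf-50. These values thus follow largely from the choice and cannot test the explanation by sequence variants. H3K27me3 at these genes stays open: 0 of the 10 were marked in a mock list, but they were chosen as expressed without clf-50 and no label names clf-50 plants for a peak list. A deletion or rearrangement carried with clf-50 is a candidate explanation, as all 10 expressed members of the run that are no pseudogene were near-silent, and the exception, AT2G23330, is a pseudogene at 335% of its level elsewhere. Genomic reads would be needed to test it.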

How the results depend on the processing

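The alternatives with the mock list of the other dose, the 5000 peaks of highest score, the lists with RLE or without a replicate, the marked genes without a replicate and the counts without the genes around CLF were chosen after seeing the data. Of the main values recomputed, 75 stayed within their spread or within 1.5 times the count, 54 moved and 1 changed direction. Of 303 values for lists none changed direction and 112 lost their call, and of values for named genes 1264 kept direction and side of the threshold, 86 gained a call, 208 lost it and 5 changed direction. The fit has 2 residual degrees of freedom, and depth limits what 0 counts can show to the floor of 3 counts. Except where fewer libraries, lists or peaks entered by construction, the cause was not tested.

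With no filter on low counts, ABA at 4 d called 12 genes in WT and 6 in the double mutant, the double mutant against WT called 2645 under ABA and 212 in mock, the interaction 3 and ABA at 5 h 70. DESeq2 gave 487, 1919, 4355, 864, 88 and 1020 in that order. Limma voom gave 2856 for the double mutant against WT under ABA and 0 at 5 h. With the mean of both mocks as control, ABA at 4 d called 18 genes in WT and 8 in the double mutant. The additive model over 10 libraries called 3870 genes for genotype in mock and 107 at 5 h. Leaving out 1 ABA library of 4 d at a time gave 0 to 326 genes for ABA in WT, 0 to 4357 in the double mutant, 0 to 6663 between genotypes under ABA, 0 to 24 for the interaction, 0 to 1001 in mock and 0 to 1059 at 5 h.

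With the replicate number of the ABA libraries as a block, 0 genes were called between genotypes under ABA, with 6886 at an unadjusted p under 0.05. The deviations of same-numbered replicates correlated at −0.042, so the numbers do not pair the libraries and the block was not used. For the H3K27me3 lists at 5 h the block of same-numbered pairs gave an overlap difference of 0.0203, against −0.0147 to 0.0155 when each list was left out in turn.

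With a mean of at least 1 CPM the single libraries differed at 2168 genes for ABA at 5 h in the double mutant, 1061 in clf-50, 386 in swn-1 and 2883 in the double mutant in mock. Of 53 list calls out of 108, 0 remained with an estimated correlation and 0 with fry, 54 were made with RLE and 54 to 59 without 1 replicate. Among the 50% of peaks with the highest score in each list, 1 was gained and 1 lost with 50 µM, and 1 and 1 with 100 µM. Against the other mock list 139 peaks were gained and 724 lost with 50 µM and 1613 gained with 100 µM. Among the 5000 peaks of highest score, 304 were gained and 173 lost with 50 µM and 274 and 157 with 100 µM, while between replicates at 5 h the counts were 54 and 257 for mock and 91 and 279 for ABA.

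Direction changed for the marked minus unmarked induced genes in the interaction, to 0.16 at a log2 ratio of at least 2. Against the mock library of 5 h it changed in the double mutant for PYL5 (0.37), ASN1 (2.1) and SEN1 (1.37), and in the interaction for LDOX (−0.31). Against the mean of both mocks ASN1 lay at 0.13. The odds ratio of marked genes under ABA had no value without either WT replicate, where no gene was called.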

Other observations

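Under 4 d of ABA the list of ABA synthesis and breakdown genes was not called between the double mutant and WT. Adjusted over the list alone, NCED9 (4.49 ± 0.86) and the ABA-aldehyde oxidase gene AAO3 (2.41 ± 0.47) rose and CYP707A2 (−1.27 ± 0.26), an ABA breakdown gene, was lower, against NCED9 alone over all genes. Among embryo and seed maturation genes the same adjustment gave 4 higher, ABI5 (2.11 ± 0.41), EM6 (2.41 ± 0.49), EM1 (4.75 ± 1.06) and OLEO2 (2.82 ± 0.75), and 1 lower, AGL15 (−1.62 ± 0.44). In the interaction the cold-regulated genes KIN1 (−3.32 ± 0.78) and COR15A (−2.87 ± 0.67) had the smallest p of the ABA-responsive list and did not pass either threshold.

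Genes that gained H3K27me3 with both doses at 4 d also included ORA59, a regulator of jasmonate and ethylene defence, and SLY2, a gibberellin signalling F-box gene, while the microRNA genes MIR156d and MIR396a lost it, each covered over 100% of its length in both mock lists and 0 in both ABA lists. These genes were chosen after their values were seen. Of the genes gained and lost with both doses, 20 of 39 and 5 of 11 also separated the replicates of the same treatment at 5 h. Between the WT replicates after 4 d of ABA the median of the ABA-responsive list differed by −0.81 and that of the senescence list by −0.68.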
